A study of Mus musculus with 6 samples.

How the data were processed

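Total RNA from pooled mouse placentae at 9.5 days post coitum was labelled with biotin and hybridised to Affymetrix 3' expression arrays, per the labels. The values are signal intensity on a linear scale, deposited as 1 table per array type, and the submitters' processing notes name MAS5 and GCOS, with versions not given in the sources used here. The trimmed mean (2% of values removed at each end) of every column lay between 500.0 and 500.2, so each array had been scaled alone. No column of values was left unused, and no detection calls were used here, so a low signal could not be told from background. Signals under 16 made up 4.48% to 15.6% of the probe sets on an array.

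Probe sets were joined by identifier. Of 45037 probe sets common to both replicates, 22626 were on MOE430A, 22511 on MOE430B and 100 on both, which were averaged. Gene names came from the platform annotation, updated through gene identifiers in a RefSeq table of assembly GRCm38.p6, used only for names and for which genes lie near each other. A single symbol was given for 34945 probe sets, several for 932 and none for 9160, and only probe sets with 1 symbol were named; 34741 matched the RefSeq table. MOE430B signals were 4.77 times those of MOE430A for the same probe sets and wildtype RNA (median), so every tested difference was a ratio within a table. Levels of different tables did enter the filter on mean signal and the choice of a probe set per gene, which therefore favour probe sets of MOE430B, and the alternatives normalized across the 4 pools.

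Ratios were computed as log2(signal + 16). Probe sets with a mean log2 signal over the 4 pools at or above the median were tested (22519) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The replicate number was a block, because it is also the array type per the series design. Same-numbered pools deviated together from their genotype means (r = 0.91 across probe sets), which the array type alone can give. The fit had 1 residual degree of freedom and 7.16 prior degrees of freedom, so p-values rest largely on the spread shared between probe sets. Pool and array type cannot be separated.

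Each gene was represented by the single-gene probe set with the highest mean log2 signal, with _x_at probe sets used only where no other existed. The named genes were all Ehmt2 probe sets and Ehmt1; the 12 highest and 12 lowest mean log2 ratios among genes that passed and moved the same way in both pools; all measured genes of the Kcnq1 and Igf2r domains, Igf2 and H19; of every other list up to 4 members with the largest absolute ratio and every member that passed; and the 3 genes with the largest opposite ratios. The 22 lists, the designs, this rule and most alternatives were set before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists with at least 3 measured members. Camera with an estimated correlation and fry, which tests whether the genes of a list change without comparing them with other genes, were alternatives. With 1 residual degree of freedom the estimated correlation is itself poorly determined. Camera then also takes its p-values from that 1 degree of freedom, which leaves little power. Fry for a shift one way rests on it too. A list that did not pass these alternatives was therefore not shown to be unchanged. Other alternatives were the pseudocount, scaling, filter, variance trend, the replicate block left out after quantile normalization across the 4 pools, array, fold threshold, window and each replicate left out. Genes called measured are those over the signal filter. The Y-linked list had 1 measured gene and was given no test.

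The fit was tested on simulated data built for the comparison of G9a-/- with wildtype from the real levels and spread of 22519 probe sets, with 200 changed in each of 20 draws. With 1 SD per signal level, 59.0% of 2-fold, 99.5% of 4-fold and 100% of 16-fold changes were recovered and 10.1% of calls were false. With SDs varying between probe sets, 15.9%, 80.0% and 99.0% were recovered and 12% of calls were false. The adjusted p threshold of 0.05 is therefore too lenient by about that excess. For 200 unshifted simulated lists, camera gave an unadjusted p under 0.05 for 7. The simulated noise was independent between probe sets, so this does not test camera on lists whose genes vary together.

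Precision was also read from repeated measurement. For the 100 probe sets on both first-pool arrays, the log2 ratios of MOE430A and MOE430B differed with an SD of 0.27, against 0.37 between MOE430A and Mouse430_2, which differ in pool as well. Over all tested probe sets the ratios of the pools differed with a larger SD, 0.60, so these 100 do not stand for the rest. The ratio of 3' to 5' signal of the actin control, a sign of RNA integrity, was 1.43 and 1.50 on MOE430A, 1.45 and 1.40 on MOE430B, and 1.61 and 1.20 on Mouse430_2, for G9a-/- and wildtype respectively. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.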

Results

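Placental RNA was compared between mouse conceptuses lacking G9a (gene symbol Ehmt2), a histone methyltransferase that places mono- and dimethyl marks on lysine 9 of histone H3, and wildtype conceptuses at 9.5 days post coitum. The G9a allele was a gene trap, an inserted reporter cassette with a splice acceptor. Each genotype was represented by 2 biologically separate pools of placentae. The first pool of each genotype was measured on the MOE430A and MOE430B arrays and the second on the Mouse430_2 array, giving 6 arrays in all. Median signal intensity was 185 and 183 on MOE430A, 264 and 274 on MOE430B, and 108 and 126 on Mouse430_2, for G9a-/- and wildtype respectively. The number of arrays limits the precision of every value below. Ratios are G9a-/- over wildtype on the log2(signal + 16) scale, which understates the change of low signals, and are means ± SD of the 2 pools' ratios.

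The targeted gene was examined first. Ehmt2 signal fell in both pools, by 57.6-fold on the scale used (1460692_at, log2 ratio -5.85 ± 0.61, SD, n = 2 pools; limma adjusted p = 6.4e-05). Its signal was 15.6 against 1333 in pool 1 and 41.4 against 4443 in pool 2. The other Ehmt2 probe set (1426888_at) lay under the signal filter and had a log2 ratio of -4.04 ± 1.30, with a limma adjusted p of 0.059 when fitted without the filter. Ehmt1, which encodes the partner methyltransferase GLP, had a log2 ratio of -0.05 ± 0.29 (limma adjusted p = 0.92). A probe upstream of the trap insertion, or in sequence kept in the fusion transcript, would not report on the allele, and the position of the insertion was not used here.

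The first comparison asked which genes differed between G9a-/- and wildtype placentae. Magea5 and Magea6, members of a family normally expressed in the testis, rose with log2 ratios of 5.64 ± 1.25 and 4.25 ± 0.86. Gtsf1 and Asz1, which act in transposon silencing in germ cells, rose with ratios of 4.52 ± 0.26 and 4.23 ± 0.04. Nppb, which encodes B-type natriuretic peptide, and Adm, which encodes the vasodilator adrenomedullin, rose with ratios of 5.19 ± 0.43 and 4.26 ± 1.19. The other genes in the top 12 were 1700080O16Rik, 1700013H16Rik, 1700018B24Rik, AI662270, Efhc2 and Pfpl, with ratios from 4.10 for Pfpl to 5.18 for 1700080O16Rik.

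At the other end, the placental cathepsin genes Ctsj and Ctsr fell with log2 ratios of -6.00 ± 1.06 and -5.43 ± 1.81. Prl2b1, a placental member of the prolactin family, fell with a ratio of -4.84 ± 1.29. Tpbpa, a marker of spongiotrophoblast and its precursors, fell with a ratio of -2.37 in each pool on its brightest probe set and with means of -1.58 and -1.43 on the others, the last without passing. Gjb2, which encodes the gap junction protein connexin 26 of the labyrinth, fell with a ratio of -3.03 ± 0.64. Itih5 fell with a ratio of -3.82 ± 0.73 on its brightest probe set and with -1.49 and -1.68 on the others. Apela (-2.59 ± 0.33), which encodes a peptide hormone of the apelin receptor, and Pcolce (-2.48 ± 0.08), an enhancer of procollagen processing, also fell. With Ehmt2, 1700086L19Rik, Dcaf12l1 and Gpr50, these made up the lowest 12.

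In all, 563 of 22519 probe sets passed limma's adjusted p threshold of 0.05, 310 higher and 253 lower in G9a-/-. With 1 probe set per gene, 351 of 11135 genes passed, 183 higher and 168 lower. Of 27 named genes that passed and had other tested probe sets, all of these passed the same way for 17. For 10 at least 1 did not pass, and for 4 of these (Hbb-y, Sparc, Col3a1 and Egln3) none passed. Some passed and some did not for Tpbpa, Atp10a, Gab1, Slc2a3, Ttr and Csf1r. The count of 563 was 141 when the variance prior had no intensity trend, 243 after quantile normalization across the 4 pools with the replicate block kept, and 31 after that normalization without the block. In simulated data with known changes 12% of calls were false under the more variable of the noise models, more than the threshold states.

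**Figure D1:**
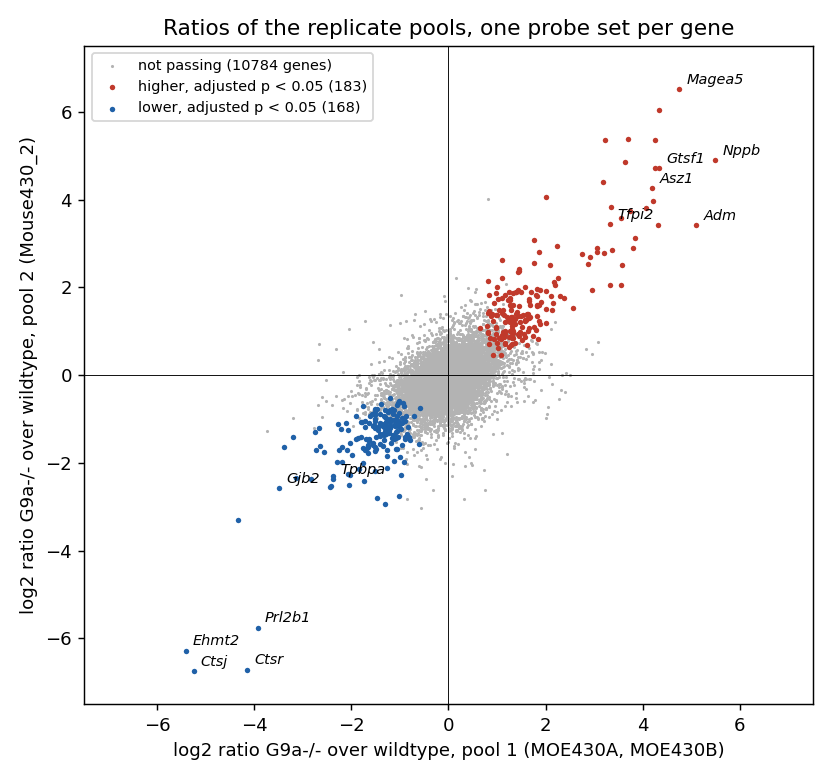
Log2 ratio of G9a-/- over wildtype in pool 1 (x axis) against pool 2 (y axis), 1 point per gene, with genes past limma's adjusted p threshold coloured. The 183 higher and 168 lower genes lie in the quadrants where both pools have the same sign, and Ehmt2 lies at -5.41 and -6.28.

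The pools were then compared without an estimate of the spread. A 2-fold change in the same direction in both pools was found for 491 probe sets, 260 higher and 231 lower, and in opposite directions for 19. Examples of disagreement were Baiap2l1, with log2 ratios of -1.71 in pool 1 and 1.22 in pool 2, Cfap126 (1.20 and -1.79) and Abca9 (-1.20 and 1.14). Across genes, which are not independent replicates, the ratios of the pools had a Pearson r of 0.57 and a Spearman rho of 0.43. Among genes with an absolute mean log2 ratio under 1, Pearson r was 0.31.

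Genes subject to genomic imprinting, expressed from only the maternal or the paternal copy, are the subject named in the study's title. Of 19 measured paternally expressed genes, 4 fell, 1 rose and 14 did not pass. Mest, an alpha/beta hydrolase gene, fell with a log2 ratio of -1.58 ± 0.10, Ndn with -1.61 ± 0.28, Dlk1, a Notch ligand homologue, with -1.27 ± 0.45, and Peg3, a zinc finger gene, with -1.02 ± 0.28. Gab1, which encodes a receptor adaptor, rose with a ratio of 0.86 ± 0.30, and Magel2 had a ratio of -1.15 ± 0.26 without passing. Adjusted over the list alone, 7 fell and 1 rose. As a list these genes lay lower than other genes (camera, preset correlation, adjusted p = 0.0083), and the adjusted p = 0.58 with an estimated correlation. The mesenchyme and erythroid lists also lay lower in the G9a-/- pools (medians -0.57 and -0.97), and a change within cells was not separated from a change in the share of cell types.

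Of 26 measured maternally expressed genes, 2 rose, 1 fell and 23 did not pass. Tfpi2, a protease inhibitor gene, rose with a log2 ratio of 3.38 ± 0.08 and Atp10a, a phospholipid flippase gene, with 2.15 ± 0.05. Asb4 fell with a ratio of -2.12 ± 1.17, and Klf14 had a ratio of -1.69 ± 1.42 without passing. Adjusted over the list alone, 3 rose and 5 fell. The list did not stand apart from other genes (camera adjusted p = 0.35).

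None of the 14 measured genes of the Kcnq1 domain passed limma's threshold over all genes, while 2 had an unadjusted p under 0.05 and 1 rose when adjusted over the list alone. Trpm5 had the largest log2 ratio (1.02 ± 0.29, limma adjusted p = 0.051), followed by Slc22a18 (-0.80 ± 0.41). Cdkn1c, which encodes a cyclin-dependent kinase inhibitor, had a ratio of -0.07 ± 0.25, Phlda2 of -0.18 ± 0.34, Ascl2 of 0.04 ± 0.36 and the noncoding RNA Kcnq1ot1 of 0.24 ± 0.09. The other Kcnq1ot1 probe sets had means of -0.41, 0.13 and 0.14, each with opposite signs in the pools. Ratios were -0.36 for Tspan32, -0.26 for Cd81, -0.15 for Tssc4, -0.08 for Nap1l4 and -0.02 for Tnfrsf22. They were 0.12 for Cars, 0.23 for Dhcr7 and 0.27 for Tnfrsf23. The list had a camera adjusted p of 0.77. Kcnq1, Osbpl5 and Th lay under the signal filter, and Tnfrsf26 had no probe set named for it alone. In the Igf2r domain, Igf2r had a ratio of 0.15 ± 0.37 and the noncoding RNA Airn of -0.03 ± 0.71, and 2 measured genes were too few for a list test. Other probe sets had means of -0.10 for Igf2r and of -0.52 and -0.35 for Airn. Slc22a2, Mas1 and Plg lay under the signal filter, and Slc22a1 and Slc22a3 had no probe set named for them alone, so this domain was hardly covered. Igf2, a growth factor gene, had a ratio of -0.10 ± 0.11, and H19 was not named here because its probe set carries more than 1 symbol. The signals sum both parental copies, so these ratios do not measure allelic expression, and the signs of Cdkn1c, Tnfrsf22, Airn and Igf2 turned under quantile normalization.

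**Figure D2:**
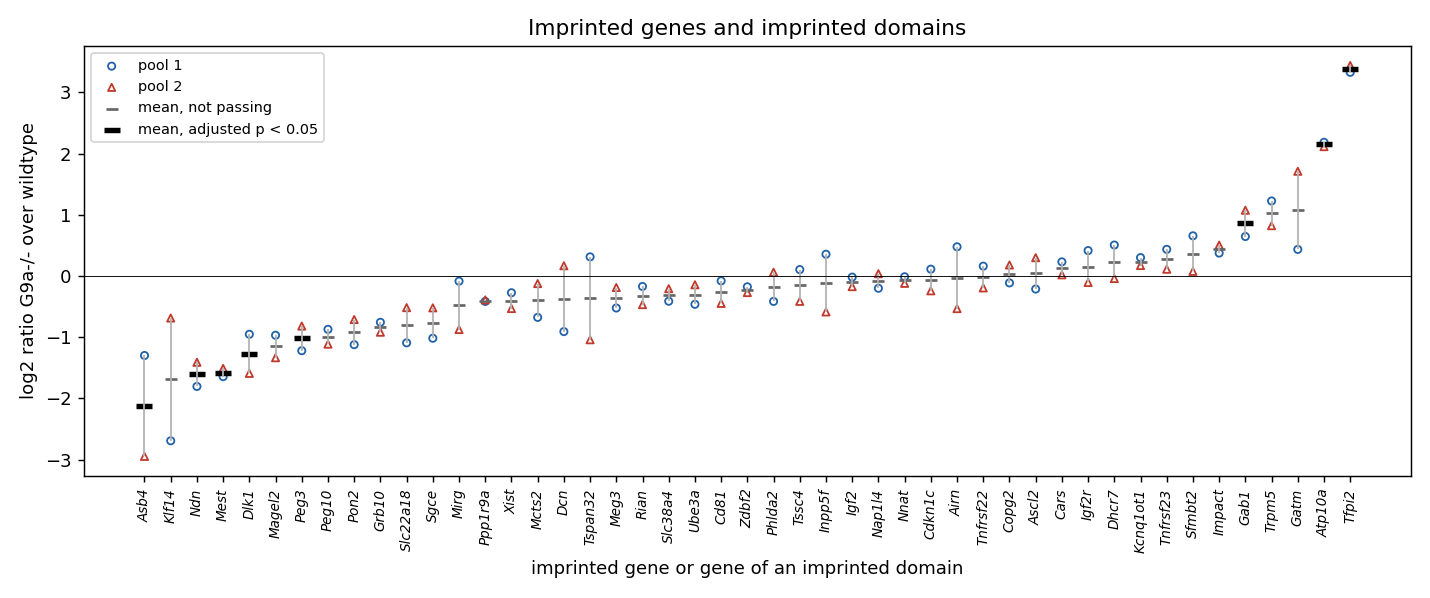
Log2 ratio of G9a-/- over wildtype (y axis) for 47 imprinted genes and genes of imprinted domains (x axis), with pool 1 as circles, pool 2 as triangles and the mean as a bar. The means of 8 genes passed limma's threshold, 3 of them higher (Tfpi2, Atp10a, Gab1) and 5 lower (Asb4, Ndn, Mest, Dlk1, Peg3).

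Of 11 germline and cancer-testis genes over the signal filter, 8 rose, 0 fell and 3 did not pass, and 8 rose when adjusted over the list alone. Besides the Mage genes, Gtsf1 and Asz1, Sohlh2, a germ cell transcription factor gene, rose with a log2 ratio of 3.59 ± 0.35, Syce1, a synaptonemal complex gene, with 2.34 ± 0.66, and Wfdc15a with 1.96 ± 0.06. Dazl, which encodes a germ cell RNA-binding protein, rose with 2.05 ± 0.35 on its brightest probe set and with 5.36 on another. The median of these 11 was 2.34 (camera adjusted p = 1.1e-12), and the adjusted p = 0.58 with an estimated correlation. The filter takes the mean over both genotypes, so a gene low in wildtype stays in if its G9a-/- signal is high, and 19 of the 30 members named on the arrays were left out. Over all 30 with no filter, 7 rose and 0 fell, 10 were higher at an unadjusted p under 0.05, and the median was 0.56 (camera adjusted p = 8.7e-09; adjusted p = 0.63 with an estimated correlation).

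Markers of the cell types that a dissected placenta holds were then compared. Of 15 measured visceral endoderm and yolk sac genes, 7 rose and 8 did not pass; adjusted over the list alone, 13 rose. Fgg, a fibrinogen chain gene, rose with a log2 ratio of 2.12 ± 0.10, Apoa4 with 1.91 ± 0.36, Apoc2 with 1.69 ± 0.05, Cubn with 1.37 ± 0.51, Afp, which encodes alpha-fetoprotein, with 1.34 ± 0.19, Amn with 1.26 ± 0.31 and Ttr with 1.11 ± 0.33. The list lay higher than other genes (median 1.11, camera adjusted p = 2.4e-12), and the adjusted p = 0.58 with an estimated correlation.

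Erythroid genes lay lower (median -0.97, camera adjusted p = 1.9e-06; adjusted p = 0.58 with an estimated correlation). Of 12 measured, 4 fell and 8 did not pass, and 9 fell when adjusted over the list alone. The embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y fell with log2 ratios of -1.23 ± 0.76, -1.18 ± 0.48 and -1.05 ± 0.37, and Hemgn with -1.55 ± 0.59. The other probe sets of Hbb-y had ratios of -0.52 and -0.43 and did not pass. Slc4a1, which encodes the band 3 anion exchanger, had a ratio of -1.06 ± 0.24 without passing on its representative probe set, and its other probe set passed with -1.35. Mesenchyme and matrix genes also lay lower (median -0.57, camera adjusted p = 3.6e-05; adjusted p = 0.66 with an estimated correlation). Of 18 measured, 5 fell, and 8 fell when adjusted over the list alone. Pdgfrb, a receptor of pericytes, fell with a ratio of -2.16 ± 0.14, Postn with -1.45 ± 0.07, Col3a1 with -1.25 ± 0.04, Acta2 with -0.97 ± 0.11 and Sparc with -0.82 ± 0.16 on its brightest probe set, while the others of Sparc did not pass (-0.28 and -0.07). Tagln had a ratio of -1.0 ± 0.82.

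Of 18 measured labyrinth and syncytiotrophoblast genes, 4 fell and 1 rose; adjusted over the list alone, 12 fell and 2 rose. Besides Gjb2, Met, the receptor of hepatocyte growth factor, fell with a log2 ratio of -2.31 ± 1.27, the homeobox gene Esx1 with -1.39 ± 0.48 and Rhox9 with -0.79 ± 0.21. Slc2a3, a glucose transporter gene, rose with a ratio of 0.88 ± 0.08, and Cebpa had a ratio of -1.30 ± 0.63. The list median was -0.62 (camera adjusted p = 0.00041; adjusted p = 0.58 with an estimated correlation). Of 15 measured spongiotrophoblast and glycogen cell genes, 5 fell and 1 rose; adjusted over the list alone, 7 fell and 2 rose. Besides Tpbpa, the prolactin family genes Prl8a9, Prl6a1 and Prl7b1 fell with ratios of -2.28 ± 0.32, -1.72 ± 0.08 and -1.66 ± 0.57, and Car2 with -0.86 ± 0.49, while Prl5a1 rose with 3.49 ± 0.50. The list had a camera adjusted p of 0.030, the adjusted p = 0.59 with an estimated correlation, and the call was lost with a pseudocount of 1, without a trend, and with all probe sets of a gene averaged.

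Of 12 measured trophoblast stem cell genes, Elf5 rose with a log2 ratio of 1.18 ± 0.27, Sox21 fell with -1.44 ± 0.62 and 10 did not pass, with Cdx2 at 0.76 ± 0.22 and Bmp4 at -1.13 ± 0.81. The counts were the same when adjusted over the list alone, and the camera adjusted p was 0.30. Of 14 fixed giant cell markers, only 7 were named on the arrays. Of the 6 measured, Ctsj fell and 5 did not pass (camera adjusted p = 0.37). Ctsq lay under the signal filter with a log2 ratio of -2.71, and with no filter the camera adjusted p was 0.11. Hand1, Nos3 and Prl4a1 had ratios of 0.71 ± 0.57, -0.53 ± 0.26 and -0.34 ± 0.00, and adjusted over the list alone 1 rose and 2 fell. Of 12 measured endothelial genes, Pecam1 rose with 1.15 ± 0.43 and Ramp2 fell with -1.25 ± 0.24. Plvap and Emcn had ratios of -1.27 ± 0.38 and -1.03 ± 0.31, and the camera adjusted p was 0.74. Adjusted over the list alone, 1 rose and 3 fell.

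Maternal tissue was examined by 2 lists, though the leukocyte list also holds general leukocyte genes and is not particular to maternal cells. Of 12 measured decidual genes, Prl8a2, a decidual prolactin family gene, rose with a log2 ratio of 0.77 ± 0.09, also when adjusted over the list alone. Cryab, Des and Stc1 had ratios of 0.82 ± 0.27, 0.65 ± 0.45 and -0.53 ± 0.48, and the camera adjusted p was 0.37. The other probe set of Cryab passed with 1.28. Of 12 measured leukocyte genes, Csf1r, the macrophage colony-stimulating factor receptor gene, fell with -1.25 ± 0.10, also when adjusted over the list alone. Laptm5 had a ratio of 0.70 ± 0.61 (camera adjusted p = 0.57 for the list). The granzyme genes Gzmf and Gzmd had ratios of -2.67 and -2.33 in pool 1 and of 0.71 and 0.59 in pool 2.

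**Figure D3:**
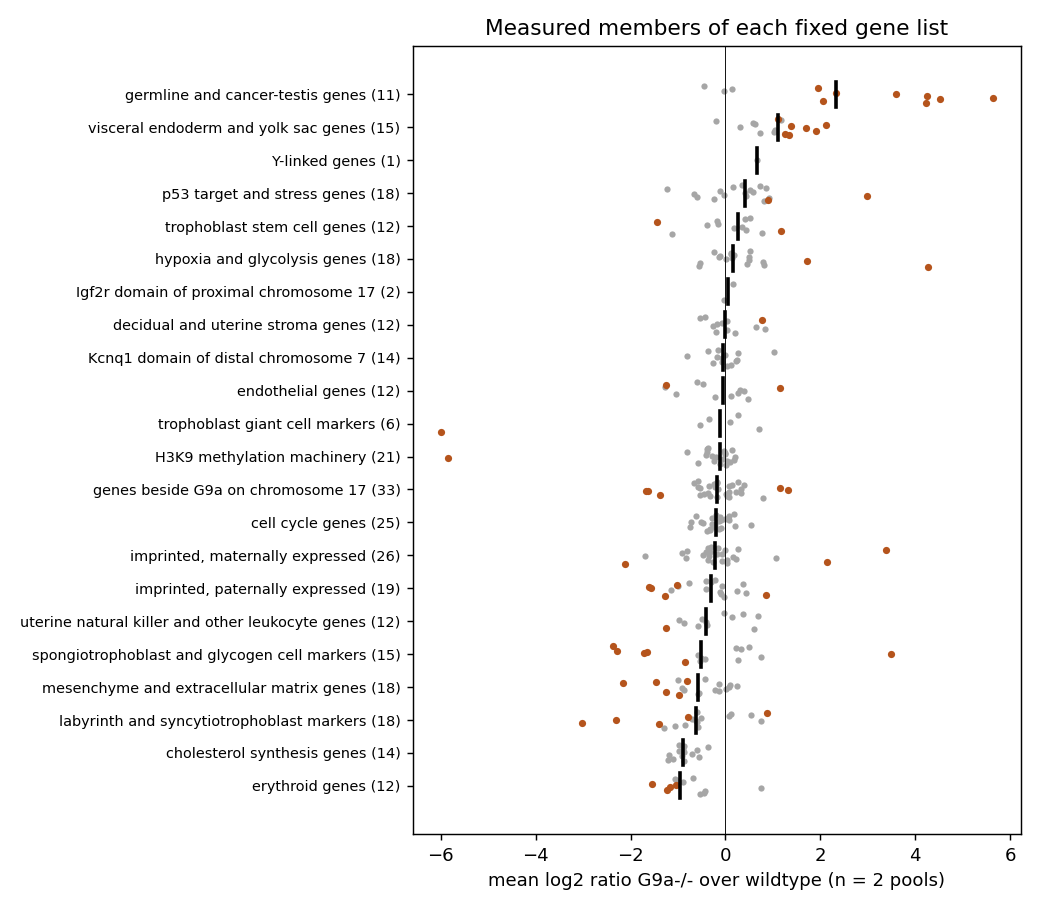
Mean log2 ratio of G9a-/- over wildtype (x axis, n = 2 pools) of each measured member of the 22 fixed gene lists (y axis, number measured in parentheses), with genes past limma's threshold in orange and list medians as black bars. Medians cover only members over the signal filter, which raises that of the germline list (2.34, against 0.56 over all 30 members with no filter), and the erythroid median is -0.97.

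All 14 measured cholesterol synthesis genes had ratios below 0 (median -0.89), and none passed limma's threshold over all genes, while 12 had an unadjusted p under 0.05 and 12 fell when adjusted over the list alone. Fdft1, Idi1, Fdps and Msmo1 had log2 ratios of -1.21 ± 0.73, -1.20 ± 0.83, -1.10 ± 0.88 and -0.99 ± 1.20. The median was -1.28 in pool 1 and -0.47 in pool 2 (camera adjusted p = 1.6e-07; adjusted p = 0.66 with an estimated correlation). Of 18 measured p53 target and stress genes, Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose with a ratio of 2.98 ± 0.13 and Asns, asparagine synthetase, with 0.90 ± 0.11. Bbc3 and Plk2 had ratios of 0.91 ± 0.19 and -1.23 ± 1.07. Adjusted over the list alone, 6 rose and 2 fell (median 0.42, camera adjusted p = 0.0018; adjusted p = 0.58 with an estimated correlation). In fits across pools with no replicate block the p53 list median fell below 0 without G9a-/- replicate 2 (-0.053) and without wildtype replicate 1 (-0.091). Differences between array types enter the ratios of those fits, so they do not separate genotype from array type. Of 18 measured hypoxia and glycolysis genes, Adm and Egln3, an oxygen-sensing prolyl hydroxylase gene (1.72 ± 0.16), rose. Ankrd37 and Egln1 had ratios of 0.80 ± 0.13 and 0.78 ± 1.25. The list median was 0.16 (0.19 in pool 1 and -0.01 in pool 2), and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.012; adjusted p = 0.58 with an estimated correlation).

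None of the 25 measured cell cycle genes passed limma's threshold, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.12 for the list). Ccnb2, Kif20a, Plk1 and Ccne2 had log2 ratios of -0.75 ± 0.60, -0.72 ± 0.50, -0.62 ± 0.60 and 0.54 ± 0.09. Among 21 measured genes of the H3K9 methylation machinery, Ehmt2 alone fell, also when adjusted over the list alone (camera adjusted p = 0.082). Suv39h2, Cbx5 and Kdm4a had ratios of -0.81 ± 0.63, -0.59 ± 0.21 and -0.41 ± 0.16. In all, 10 of 20 lists passed camera at the preset correlation, 4 higher and 6 lower. With an estimated correlation 0 of 20 did, nor did any at an unadjusted p under 0.05. The 1 residual degree of freedom made this outcome likely whatever the correlation. Estimates for the 10 lists ran from -0.09 (erythroid) to 0.71 (cholesterol synthesis), and all 10 lost their calls. With fry, 0 passed for a shift one way and 6 for change in either direction.

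The last comparison asked whether genes near G9a on chromosome 17, where DNA beside the trapped allele could differ in strain between the groups, changed more often than others. Within 20 Mb of Ehmt2, 9 of 363 genes changed 2-fold in the same direction in both pools (2.48%), against 273 of 10713 elsewhere (2.55%). The odds ratio was 0.97 (95% interval 0.44 to 1.89; Fisher's exact test, two-sided, p = 1), and genes are not independent replicates. Ehmt2 is 1 of the 9, and without it 8 of 362 changed. Of 33 measured genes of the list beside G9a, the heat shock genes Hspa1a and Hspa1b fell with log2 ratios of -1.68 ± 0.31 and -1.63 ± 0.05 and Ddah2 with -1.38 ± 0.44. Ier3 and Neu1 rose with ratios of 1.31 ± 0.01 and 1.14 ± 0.18. The same counts were found when adjusted over the list alone. These 5 of 33 were 15.2%, against 3.11% of other genes apart from Ehmt2 (Fisher's exact test, two-sided, chosen after the values were seen, p = 0.0034). The list did not shift one way (camera adjusted p = 0.30), while fry gave an adjusted p of 0.025 for change in either direction. That was not particular to it: 6 lists passed this fry test. The maternally expressed, endothelial and decidual lists had the same fry adjusted p. Hspa1a and Hspa1b are near-identical copies.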

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

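The filter on Mouse430_2 alone, the normalization across pools with the block kept and the fits leaving out 1 pool of 1 genotype were chosen after seeing the data, the rest before. All 74 named genes that passed, apart from Ehmt2, kept direction and threshold with a pseudocount of 64, quantile normalization and median centring. These settings called more probe sets, and all 563 of the main fit passed in each, so this was not particular to the named genes. All 73 tested with a pseudocount of 1 also kept direction and threshold. Without a variance trend 36 of 74 no longer passed, after quantile normalization across the 4 pools with the block kept 23 of 73, and after that normalization with no replicate block 59 of 73. The cause of changes below was not tested, apart from settings that change the number of probe sets or samples tested. With 1 residual degree of freedom, and with low signals not separable from background, the counts of calls are less certain than the directions.

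The count of differing probe sets (563) was 922 with a pseudocount of 64, 888 with quantile normalization, 1104 with median centring, 177 with no filter, 141 without a trend, 104 on MOE430B alone, 243 after quantile normalization across the 4 pools with the block kept, and 31 after that normalization with no replicate block, all 31 among the 563. The fit with no replicate block and 1 pool left out, where the lone pool is assumed to vary like the others, gave 2 to 7 calls (5 without G9a-/- replicate 1, 7 without wildtype replicate 1, 7 without G9a-/- replicate 2, 2 without wildtype replicate 2). With 1 pair left out there is no test: 1554 probe sets were 2-fold changed without replicate 1 and 1639 without replicate 2.

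The count changed 2-fold in both pools (491) was 1270 with no filter, 247 with the upper quartile filter, 303 on MOE430A, 188 on MOE430B, 1764 at 1.5-fold and 147 at 3-fold. Pearson r between pools (0.57) was 0.59 with a pseudocount of 64, 0.34 with no filter, 0.64 with the upper quartile filter, 0.62 on MOE430A and 0.49 on MOE430B.

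The Ehmt2 ratio of 1460692_at stayed below 0 in all settings. In the fits without the block that left out 1 pool, it was -4.93 without G9a-/- replicate 1 and -4.98 without wildtype replicate 2. In the same fits it was -6.40 without wildtype replicate 1 and -6.45 without G9a-/- replicate 2. With 1 pair left out it was -6.28 or -5.41. The ratio of 1426888_at was -5.64, -4.03 and -4.00, now past the threshold, with a pseudocount of 1, quantile normalization and median centring. This probe set lay under the signal filter, so it was not part of the main fit and its values come from fits with no filter. At the main settings it did not pass (-4.04, limma adjusted p = 0.059). Nor did it pass, with higher limma adjusted p, with a pseudocount of 64 (-2.58, adjusted p = 0.11), without a trend (adjusted p = 0.51) and after normalization across the 4 pools (-3.83, adjusted p = 0.070 with the block and 0.085 without). Its ratio was -3.12 to -4.96 with 1 pair left out, and -2.76 to -4.90 in the fits without the block that left out 1 pool.

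The count of lists (10) was 9 to 12 under other settings, except 0 with an estimated correlation, 0 with fry, and 5 to 13 in the fits leaving out 1 pool. The odds ratio near G9a turned from 0.97 to 1.17 with a pseudocount of 1, 1.11 with median centring, 1.33 with the upper quartile filter, 1.40 within 10 Mb and 1.02 at 1.5-fold, with Fisher p from 0.39 to 0.92 in these.

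Genes that had not passed changed sign as follows. With quantile normalization ratios were 0.0734 for Abca9, 0.127 for Cdkn1c, 0.0381 for Tnfrsf22, 0.0558 for Airn and 0.0475 for Igf2. With median centring they were 0.0263 for Abca9, 0.0266 for Tnfrsf22, 0.0291 for Airn and 0.0113 for Ehmt1. After quantile normalization across the 4 pools, with or without the replicate block, they were 0.0351 for Cdkn1c, 0.0697 for Tnfrsf22, -0.00674 for Ascl2 and 0.166 for Airn.

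Lists turned in camera's direction, which follows the members against other genes and not the median, as follows. None had passed apart from the p53 and stress list. The medians given are those of each setting, and for the Kcnq1 domain and the decidual list they were below 0 in the main fit too (-0.0414 and -0.0158). With the upper quartile filter they were -0.0656 (Kcnq1 domain) and 0.35 (endothelial), and fry put the maternally expressed list, median -0.22, the other way. With no replicate block and without G9a-/- replicate 1 they were 0.43 (endothelial), 1.00 (leukocyte), 0.17 (cell cycle) and 0.35 (beside G9a). Without wildtype replicate 1 they were -0.16 (Kcnq1 domain), -0.41 (stem cell) and -0.26 (decidual), and the p53 and stress list had a median of -0.0909 with no turn in camera's direction. Without G9a-/- replicate 2 they were -0.17 (Kcnq1 domain), -0.18 (stem cell), -0.38 (decidual) and -0.0529 (p53 and stress). Without wildtype replicate 2 they were 0.42 (endothelial), 0.43 (leukocyte), 0.0102 (cell cycle) and 0.40 (beside G9a). The fits without the block that left out 1 pool do not separate genotype from array type, so these turns may come from either.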

Other observations

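The families in this and the next paragraph, the yolk sac test, the test of germline ratios with a pseudocount of 64 and the test of Xist were chosen after the values were seen. Intervals of medians below are 95% bootstrap intervals that resample the genes of a list. They treat genes as independent and do not measure the spread between pools. Placental gene families changed in opposite directions. All 4 measured cathepsins of the placental cluster passed, with Cts7 and Cts8 higher (log2 ratios 3.74 and 2.75) and Ctsj and Ctsr lower (-6.00 and -5.43). Ctsq lay under the signal filter and was not counted. Of 12 measured prolactin family genes, 2 rose (Prl5a1 and Prl8a2) and 6 fell (Prl2b1, Prl8a9, Prl6a1, Prl7b1, Prl7d1 and Prl8a1), or 66.7% against 3.15% of all genes (Fisher's exact test, two-sided, adjusted over 6 families, p = 2.4e-09; cathepsins p = 2.9e-06). These families were picked partly because members passed, so the p-values describe these data only, and members share sequence, so probe sets can detect relatives.

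Ceacam15 and Ceacam20 rose (log2 ratios 3.94 and 2.81), 2 of 9 measured carcinoembryonic and pregnancy-specific glycoprotein genes (Fisher's exact test, two-sided, in the same adjustment, p = 0.062). Of 3 measured Rhox genes 1 fell (Fisher's exact test, p = 0.14), and none of 7 Hox genes passed limma's threshold, or an unadjusted p of 0.05. Of 7 measured granzyme genes, products of uterine natural killer cells, none passed limma's threshold and 1 (Gzmm) had an unadjusted p under 0.05, and 5 were lower in pool 1 and higher in pool 2. Gzmg had ratios of -2.04 and 1.06 and Gzmc of -1.55 and 0.76.

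Of 11 germline genes over the signal filter 8 rose past limma's threshold. Zfp42 was lower in both pools, and Tex15 and Tex19.1 differed in sign between pools. The list did not pass with an estimated correlation (camera adjusted p = 0.58), where 1 residual degree of freedom left little power. The 8 were chosen because they passed, so their ratios cannot decide whether signals near the floor contributed. With a pseudocount of 64, which shrinks ratios of low signals, the count of probe sets moved from 563 to 922. All 8 passed there, with a median log2 ratio of 3.31 (interval 1.85 to 4.10) against 3.91 with the pseudocount of 16. All 563 probe sets of the main fit passed there too, so this outcome was not particular to the 8. The size of single ratios depends on the pseudocount, as Magea6 had 3.26 against 4.25. The median percentile of the G9a-/- signal of the 8, 92.3 among probe sets of its array, was partly set by the filter and the call. That of the wildtype signal was 41.6. Primordial germ or other pluripotent cells stay open. The median log2 ratio of 7 measured markers was 0.46, with an interval from -0.49 to 0.84. That median lay below the level set beforehand as speaking against such cells, but the interval reached above it. Members went both ways, with Dppa4 at 1.09 and Kit lower at -1.40. Pou5f1, Nanog, Dppa3, Prdm14, Nanos3, Dnd1 and Tdgf1 were also in the set and were not measured. Loss of silencing in placental cells by G9a is a hypothesis that may account for the pattern and was not tested apart from the genotype.

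Of the cell type lists, the endoderm, erythroid, mesenchyme, labyrinth and spongiotrophoblast lists passed with camera's preset correlation, and the decidual, leukocyte, endothelial, stem cell and giant cell lists did not. None passed with an estimated correlation (lowest camera adjusted p = 0.58), a test with little power at 1 residual degree of freedom. The endoderm list had a median of 1.11, with an interval over its genes from 0.62 to 1.38, and 14 of 15 members above 0. A larger share of yolk sac or endoderm tissue in the G9a-/- pools could account for this, as could higher expression within the same cells. The decidual median was -0.0158 with an interval from -0.23 to 0.43 and the leukocyte median -0.41 (-0.73 to 0.26). Both medians lay below the level set beforehand as speaking against more maternal decidua. That explanation stays open, since both intervals reached above the level and leukocyte genes are not particular to maternal cells. The pools differed beyond the leukocyte interval, with a leukocyte median of -1.24 in pool 1 and 0.59 in pool 2. A smaller share of vessels, mesenchyme and blood together also stays open. The endothelial median was -0.053 (-0.82 to 0.35), the mesenchyme median -0.57 and the erythroid median -0.97. The endothelial median lay above the level set beforehand as speaking against this explanation, but its interval reached below that level. A difference in developmental stage between genotypes was not tested.

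X-linked genes made up 3.37% of measured genes, 6.04% of those higher (11 of 182; Fisher's exact test, adjusted over both directions, p = 0.058) and 11.3% of those lower (19 of 168; p = 7.3e-06). Another ratio of male to female placentae may contribute and cannot be told apart from the genotype here. Eif2s3y, the 1 measured Y-linked gene, had log2 ratios of 0.07 and 1.25 (mean 0.66), and Xist of -0.27 and -0.53 (mean -0.40), neither passing.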
